A study of Homo sapiens with 30 samples.

How the data were processed

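Gene expression was measured on 30 Affymetrix 3 prime expression arrays of human plasmacytoid dendritic cells (pDCs), the main producers of type I interferon among blood cells. The cells came from 4 healthy donors. They were left untreated or were exposed for 3 h to gardiquimod, an agonist of Toll-like receptor 7 (TLR7), or to ODN2216, an oligonucleotide agonist of TLR9. Each ligand was used with or without an inhibitor of Bruton's tyrosine kinase (BTK) that the labels do not name. Per the labels' protocols, all RNA integrity numbers were above 6 and 100 ng of total RNA per array was amplified and labelled. The values are log2 signal intensities that the authors made with RMA (robust multi-array average), per the submitters' processing notes, which give no software or version. The values ran from 1.14 to 13.30 with array medians between 5.38 and 5.75, as log2 RMA values do, and no value was missing.

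The table held 18935 probe sets, which is only a part of those on the platform, and how they were chosen is not stated. TLR9 and several other genes of interest (CCL3, FOS, CD83, CCR7) were not in the table and were not analysed here. Of the probe sets, 16455 had 1 gene symbol, 449 had several and 2025 had none. Probe sets with several symbols or none were not tested, and 12 probe sets of XIST or Y-linked genes were left out. For each gene the probe set with the highest mean over all arrays was used, which gave 9570 genes. No detection calls were used, so a fold change from a level near the lowest values of the table is not a bound. No genome coordinates were used. The number of arrays, not a read depth, limits the precision.

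Arrays of the same donor and treatment were averaged, which gave 19 values: 4 donors untreated, 4 with gardiquimod, 4 with ODN2216, 4 with gardiquimod and inhibitor, and 3 with ODN2216 and inhibitor. The labels do not say whether the 2 arrays of a donor and treatment were separate cultures. The labels give no run or scan batch. All groups were fitted together with limma 3.58.1 (R 4.3.3) with group and donor as terms, which left 11 residual degrees of freedom, followed by empirical Bayes moderation. Tests were two-sided, p values were adjusted by Benjamini and Hochberg over the genes tested, and the threshold was an adjusted p of 0.05 with no fold threshold. Values are log2 fold changes ± standard error (SE) of the fit unless stated otherwise. The donor numbers were checked on residuals from the treatment means: the median correlation was 0.29 over 36 pairs of values of the same donor number and -0.10 over 108 pairs of different numbers.

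The 6 comparisons were each ligand with untreated, each ligand with inhibitor with the ligand alone, the difference between these inhibitor effects, and ODN2216 with gardiquimod. There were 23 gene lists, written before the data were examined: interferons, interferon-stimulated genes, inflammatory cytokines, chemokines, maturation, NF-kB, immediate-early genes, Toll-like receptor signalling, BTK and ITAM (immunoreceptor tyrosine-based activation motif) signalling, pDC identity, unfolded protein response, cholesterol synthesis, glycolysis, apoptosis, ribosomal proteins, and markers of 8 other cell types (B cells, monocytes, T cells, NK cells, conventional dendritic cells, platelets, erythroid cells and basophils). Lists were tested with limma's camera with a preset correlation of 0.01 between genes, again with an estimated correlation (statmod 1.5.0), and with fry, adjusted over 126 tests. Camera compares a list with the other genes, and fry tests whether the genes of a list move, on balance, one way. Few members were measured for ribosomal proteins (3 of 22), B cells (4 of 12), conventional dendritic cells (3 of 10), erythroid cells (1 of 10) and basophils (1 of 8), and the last 2 lists had no camera test.

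The rule for named genes was fixed before the data were examined. It took BTK, TLR7, TLR9, IRF7 and IFNB1, then up to 8 genes in each direction with the largest change among those past the threshold and changed alike in all donors. For each list described, it took up to 4 members with the largest change, and where fewer than 8 genes passed, the 5 with the smallest p. No gene was named from a probe set with several symbols. Probe sets of the IFNA genes and of IFNL2 can cross-hybridise with close relatives, so their values are not those of single genes.

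The share of a response kept with the inhibitor was computed per donor as the mean change of a list with ligand and inhibitor divided by that with the ligand alone. Both changes are on the log2 scale against untreated cells, which had no inhibitor. The share is given with its SD and was not tested. An exact sign-flip test over 3 or 4 donors cannot reach 0.05. Correlations across genes were repeated with the shared arrays divided between the comparisons and with simulated unchanged groups (100 draws).

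Alternatives fixed before the data were examined were no replicate block, all probe sets, the mean over a gene's probe sets, leaving out the 30% dimmest genes, centring each array on its median, another quantile normalization, each array as a sample with a random block, trended and robust moderation, only the compared groups, each donor left out in turn, and a log2 fold change of at least 1. A platelet marker mean as a covariate and a comparison of inhibitor effects per donor, which does not pair the donors, were chosen after seeing the data. Other splits of the samples were counted for each comparison. The fit was tested on simulated data with 200 of 9570 genes changed. For a log2 change of 1 it recovered 50.7% of changed genes for gardiquimod against untreated, 59.7% for ODN2216 against untreated, 25.4% for the inhibitor under ODN2216, 29.9% for the inhibitor under gardiquimod, 7.5% for the difference between inhibitor effects and 49.3% for ODN2216 against gardiquimod. For a log2 change of 2 the shares were 90.9%, 87.9%, 90.9%, 86.4%, 65.2% and 97% in the same order. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).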

Results

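Transcript levels of pDCs were measured on 30 arrays after 3 h in culture. There were 8 arrays of untreated cells (4 donors), 7 with gardiquimod (4 donors), 7 with ODN2216 (4 donors), 4 with gardiquimod and BTK inhibitor (4 donors) and 4 with ODN2216 and inhibitor (3 donors). Array medians lay between 5.38 and 5.75 on the log2 scale. The 11 pairs of arrays of the same donor and treatment had a median correlation of 0.93, and arrays of different donors with the same treatment had 0.89. The first principal component held 52.5% of the variance. Its mean score was -56.7 ± 3.4 (SD, n = 4) for untreated cells, -21.0 ± 13.9 (n = 4) for ODN2216 and 55.8 ± 3.4 (n = 4) for gardiquimod. With the inhibitor it was -44.9 ± 9.9 (n = 3) for ODN2216 and 55.5 ± 4.7 (n = 4) for gardiquimod.

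The comparison of gardiquimod with untreated cells describes the response to the TLR7 ligand. All 11 measured interferon genes and all 39 interferon-stimulated genes rose. IFNB1, which encodes interferon beta, rose by 10.32 ± 0.53 on the log2 scale (adjusted p = 2.46e-09, 4 of 4 donors). The probe sets of IFNA1 (10.58 ± 0.74), IFNA10 (10.25), IFNA2 (10.02), IFNA5 (9.75), IFNA21 (9.27) and IFNA8 (9.25) were also among the genes with the largest rises. Among interferon-stimulated genes the largest rises were those of IFIT1 (7.33 ± 0.65), HERC6 (6.59), RSAD2 (6.51) and CMPK2 (6.17). Of 14 inflammatory cytokines 12 rose and 1 fell, led by IL6 (7.80 ± 0.38), IL12B (6.44), LTA (5.84) and IL12A (5.70). Of 14 chemokines 12 rose and 1 fell, with CXCL10, which attracts T cells, at 9.07 ± 0.54, CCL4 at 7.30, CXCL9 at 6.62 and CXCL3 at 6.12. Of 16 maturation genes 12 rose and 2 fell, including rises of CD274 (6.01), which encodes the checkpoint ligand PD-L1, LAMP3 (5.95), CD69 (5.14) and the costimulatory CD80 (4.82). Of 17 NF-kB genes 12 rose, among them BCL2A1 (5.79), REL (4.12) and TRAF1 (4.11). Of 22 immediate-early genes 12 rose and 1 fell, with ATF3 at 5.47, NR4A3 at 4.87 and MYC at 4.28. Of 14 apoptosis and survival genes 8 rose and 1 fell. They included the survival genes BCL2L1 (4.15) and PIM1 (3.29) and the death-promoting BCL2L11 (3.87) and PMAIP1 (2.83). Camera passed for each of these 8 lists. With an estimated correlation it held for cytokines (adjusted p = 0.0197), chemokines (adjusted p = 0.0197) and NF-kB (adjusted p = 0.0432). The adjusted p with an estimated correlation was 0.103 for interferons, 0.0886 for interferon-stimulated genes, 0.104 for maturation, 0.299 for immediate-early genes and 0.0702 for apoptosis.

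Genes of pDC identity fell with gardiquimod: 18 of 24 fell and none rose (camera adjusted p = 7.97e-06, and 0.0373 with an estimated correlation). TCL1A fell by 3.40, the transcription factor genes BCL11A and RUNX2 fell by 3.15 and 2.46, and CLEC4C, which encodes the pDC surface marker BDCA-2, fell by 1.94 (each in 4 of 4 donors). Of 16 genes of BTK and ITAM signalling 7 fell and 1 rose, while camera did not pass for the list (adjusted p = 0.382) and fry did (adjusted p = 1.24e-05). The adaptor gene BLNK fell by 3.63, the kinase gene SYK by 3.56, INPP5D by 1.72 and BTK itself by 1.71 ± 0.27 (adjusted p = 0.000116). The largest falls over all genes were those of BAIAP2-DT (-4.69 ± 0.48), the phosphate transporter gene SLC20A1 (-3.96), ATOSA (-3.96), the TGF-beta receptor gene TGFBR2 (-3.90), LHFPL2 (-3.87), the glucose transporter gene SLC2A1 (-3.85), EEF2K (-3.84) and the chemokine receptor gene CCR2 (-3.77). Other probe sets of BAIAP2-DT gave only -0.69, -0.96 and -3.25, and those of CCR2 and EEF2K gave -1.81 and -2.31. TLR7 (-0.27 ± 0.26, adjusted p = 0.427) and IRF7 (0.18 ± 0.19, adjusted p = 0.48) did not pass, and the other probe set of TLR7 gave 0.47. The lists of markers of other cell types and of ribosomal proteins that had a camera test passed it in none of the 6 comparisons. Fry, which does not compare a list with other genes, passed with gardiquimod for conventional dendritic cell (adjusted p = 0.0209), B cell (adjusted p = 0.0408) and NK cell markers (adjusted p = 0.0415), all upwards. The list median was positive in only 2 of 4, 4 of 4 and 2 of 4 donors in the same order. Between ODN2216 and gardiquimod fry passed for conventional dendritic cell (adjusted p = 0.0249) and platelet markers (adjusted p = 0.0415), both lower with ODN2216. Here the list median was positive in 1 of 4 and 0 of 4 donors. With gardiquimod, the platelet marker GNG11 (2.23) and the NK cell marker PRF1 (1.92) rose, and the monocyte markers CSF1R (-1.69) and LYZ (-0.85) fell. In the marker lists, 1 of 4 B cell, 2 of 9 platelet, 1 of 8 NK cell and 1 of 1 basophil markers rose, and 2 of 6 monocyte and 1 of 7 T cell markers fell. Over all genes tested, 42.6% passed in this comparison. The calls of GNG11, PRF1 and LYZ were lost without the donor block. None of 3 conventional dendritic cell markers, 3 ribosomal protein genes or 1 erythroid marker passed.

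Over all 9570 genes, 1496 were higher and 2585 lower with gardiquimod (limma), of which 886 and 1594 changed at least 2-fold. The share of genes past the threshold that were lower was 63.3%. It was 47.5% (2219 higher, 2009 lower) when each array was centred on its median, which moved the median of all genes by 0.18, and 54.0% after another quantile normalization, so which direction held more genes depended on the scaling.

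The comparison of ODN2216 with untreated cells describes the response to the TLR9 ligand. IFNB1 rose by 9.14 ± 0.53 (adjusted p = 7.87e-08, 4 of 4 donors), and 10 of 11 interferon genes rose, with IFNA1 at 8.46, IFNA10 at 8.09, IFNA2 at 7.66, IFNA5 at 7.21 and IFNA21 at 7.09. Of 39 interferon-stimulated genes 35 rose and none fell, led by IFIT1 (6.91 ± 0.65), CMPK2 (5.78), RSAD2 (5.71) and IFIT3 (5.47). Of 14 cytokines 7 rose, including TNFSF10 (4.60), which encodes the death ligand TRAIL, IL6 (3.82 ± 0.38), IL1B (3.78) and LTA (3.70). Of 14 chemokines 5 rose, among them CXCL10 (8.01), CCL4 (6.14) and CXCL9 (4.60). Of 16 maturation genes 6 rose, with CD69 at 5.54, CD274 at 4.27, LAMP3 at 2.93 and CD40 at 2.54. Of 17 NF-kB genes 7 rose, including BCL2A1 (4.43), TRAF1 (1.96), NFKBIZ (1.75) and NFKB1 (1.56). Of 14 apoptosis genes 6 rose, with PMAIP1 at 2.11 and PIM1 at 1.57. Of 22 immediate-early genes 4 rose, namely ATF3 (5.05), NR4A3 (3.24), DUSP5 (1.74) and JUNB (1.27). Camera passed for these 8 lists. With an estimated correlation it held for all but the immediate-early list (adjusted p = 0.176).

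CCR2 fell with ODN2216 by 2.29 ± 0.42. Lower transcripts also included LINC00865 (-1.73), PLAC8L1 (-1.54), GPR18 (-1.53), SCAMP5 (-1.50), TXNIP (-1.47), ZKSCAN3 (-1.47) and SNX18 (-1.44). None of 24 pDC identity genes and none of 16 BTK and ITAM signalling genes passed the test, and BTK changed by -0.50 ± 0.27 (adjusted p = 0.531). IRF7 rose by 0.78 ± 0.19 (adjusted p = 0.0407), a call that was lost without the donor block and without any 1 of the 4 donors (8 of 13 settings in all), while TLR7 changed by 0.69 ± 0.26 (adjusted p = 0.28). In all, 223 genes were higher and 24 lower (limma). The calls of GPR18, LINC00865, PLAC8L1 and ZKSCAN3 were lost without the donor block, and those of GPR18, PLAC8L1, ZKSCAN3, SNX18, TXNIP, LAMP3, NFKBIZ, JUNB and PIM1 without at least 1 donor. The higher count fell to 128 without replicate 2. The lower count was 10 without replicate 2, 11 without replicate 3 and 6 without replicate 4, and 9 without the donor block.

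**Figure D1:**
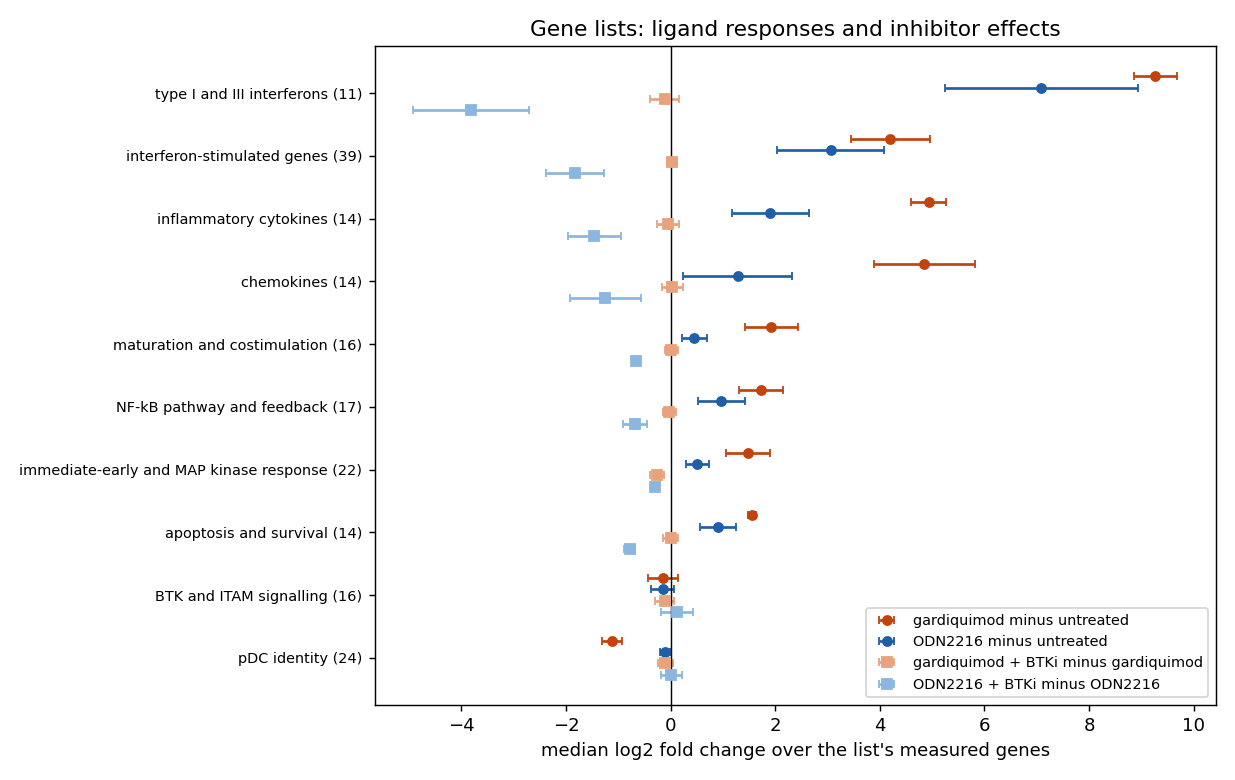
Median log2 fold change over the measured genes of each list (number in brackets) for the ligand responses (circles) and the inhibitor effects (squares), with bars of 1 SD between donors. The interferon list lies at 9.27 for gardiquimod and 7.09 for ODN2216, and at -3.81 for the inhibitor under ODN2216 and -0.11 under gardiquimod.

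Of the 223 genes higher with ODN2216, 213 were also higher with gardiquimod. Of the 24 lower genes, 23 were also lower with gardiquimod. No gene passed in opposite directions. These comparisons share the untreated arrays. Across genes, which are not independent replicates, the responses correlated with r = 0.74 (covariance 0.48), and with r = 0.68 (covariance 0.46) when different untreated arrays were used for each. Simulated unchanged groups that shared arrays gave r = 0.50 with a covariance of 0.04. The divided untreated arrays came from the same donors, and no simulation was run for them.

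The direct comparison of ODN2216 with gardiquimod shows where the ligand responses differed at the doses used, which the labels do not give. Of 14 cytokines 9 were lower with ODN2216 and 1 was higher, and the genes of the interleukin-12 subunits IL12B (-4.77 ± 0.33) and IL12A (-3.55) and of IL6 (-3.99) were among the lower. Of 14 chemokines 10 were lower and 1 was higher, including the neutrophil attractants CXCL3 (-4.77), CXCL1 (-4.53) and CXCL8 (-3.47) and also CCL5 (-3.40). Of 11 interferon genes 10 were lower, with the type III interferon IFNL1 at -4.42 ± 0.70, IFNL2 at -4.20, IFNA8 at -3.33 and IFNA16 at -2.74, whereas IFNB1 (-1.18 ± 0.53, adjusted p = 0.107) did not pass. The IFNB1 signal with gardiquimod ran from 12.51 to 13.05 between donors, near the highest value measured (13.30). Signal saturation thus stays open for IFNB1. Of 39 interferon-stimulated genes 21 were lower and 1 was higher, among them HERC6 (-3.30) and OASL (-2.57). CD80 (-4.11), LAMP3 (-3.02) and CD86 (-2.87) were among 8 lower and 3 higher of 16 maturation genes. REL (-2.79) and TNIP3 (-3.60) were among 8 lower and 2 higher of 17 NF-kB genes. FOSL1 (-3.51) and MYC (-3.19) were among 11 lower and 2 higher of 22 immediate-early genes, and BCL2L1 (-3.23) among 6 lower and 1 higher of 14 apoptosis genes. Camera passed for these 8 lists. With an estimated correlation it held for cytokines (adjusted p = 0.0432) and chemokines (adjusted p = 0.0432), and the adjusted p was between 0.185 and 0.558 for the rest.

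Genes of pDC identity were higher with ODN2216 than with gardiquimod in 15 of 24 cases and lower in none (camera adjusted p = 1.46e-06, and 0.0291 with an estimated correlation). TCL1A was higher by 3.23, BCL11A by 2.94 and SPIB by 2.11. Of 16 BTK and ITAM signalling genes 7 were higher and 2 lower, without passing camera (adjusted p = 0.351) but passing fry (adjusted p = 4.03e-05), and BLNK (3.12), SYK (3.04), PLCG2 (1.75) and BTK (1.22 ± 0.27, adjusted p = 0.0034) were higher. TLR7 (0.95, adjusted p = 0.012) and IRF7 (0.61, adjusted p = 0.027) were also higher. Over all genes the largest differences included the higher BAIAP2-DT (3.91), TGFBR2 (3.80), SLC20A1 (3.65), LHFPL2 (3.65), EEF2K (3.47), ATOSA (3.35) and NEK6 (3.34), and the lower TFPI2 (-5.14), EXT1 (-5.11), GPR34 (-4.93), TCF7L2 (-4.76) and MAML2 (-4.68). Other probe sets of BAIAP2-DT gave 0.59, 0.78 and 2.65, that of EEF2K gave 1.23 and that of MAML2 gave -2.50. The other probe set of TLR7 gave 0.53 (unadjusted p = 0.0646 in limma). GNG11, a platelet marker, was lower by 1.95. In all, 1811 genes were higher and 1008 lower (limma). The calls of BTK, TLR7, IRF7, IFNA8, IFNA16 and GNG11 were lost without replicate 3, those of TLR7 and IFNA16 also without replicate 4, that of IRF7 without any 1 donor and after centring, and that of GNG11 also without the donor block. Without that replicate the counts were 894 and 583, and with the platelet marker mean as a covariate 1112 and 561. The covariate, chosen after seeing the data, also ended the calls of IFNL2, CCL5, TLR7, IRF7, IFNA8, IFNA16 and GNG11.

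The comparison of ODN2216 with and without the inhibitor asks how far the inhibitor changes transcripts under the TLR9 ligand. No untreated cells received the inhibitor, so an effect on resting cells cannot be told apart from one on the response. Because the labels do not name the inhibitor, effects on targets other than BTK cannot be told apart either. Interferon transcripts were lower with the inhibitor: IFNB1 (-3.42 ± 0.58, 95% interval -4.66 to -2.18, adjusted p = 0.0215, lower in 3 of 3 donors), IFNA1 (-4.73 ± 0.82), IFNA8 (-4.21), IFNA10 (-4.17), IFNA2 (-4.06), IFNA5 (-3.93), IFNW1 (-3.81) and IFNA21 (-3.57). Of 11 interferon genes 8 fell, and 11 adjusted over the list alone. IL6 fell by 3.09 ± 0.42 (interval -3.98 to -2.20, adjusted p = 0.0074), LTA by 2.41 and TNF by 2.03, the 3 of 14 cytokines past the threshold (9 adjusted over the list alone). CXCL10 fell by 3.03, CXCL9 by 3.00 and CCL4 by 2.47, the 3 of 14 chemokines that passed (7 adjusted over the list alone). Of 16 maturation genes 3 fell (6 adjusted over the list alone), among them CD274 (-2.76) and CD69 (-2.10). TRAF1 fell by 1.52 and was the 1 of 17 NF-kB genes that passed (10 adjusted over the list alone), with BCL2A1 at -2.04 (adjusted p = 0.0529). Of 39 interferon-stimulated genes 4 fell, and 35 adjusted over the list alone. The members with the largest changes missed the threshold over all genes: EPSTI1 was at -2.99 (adjusted p = 0.0532), RSAD2 at -2.57 (0.082), PARP9 at -2.56 (0.0677) and HERC6 at -2.52 (0.0877). Camera passed for these lists, for immediate-early genes (1 of 22 fell) and for apoptosis (none of 14 passed singly). With an estimated correlation, camera held for cytokines (adjusted p = 0.0197), chemokines (adjusted p = 0.0342) and NF-kB (adjusted p = 0.0342). The adjusted p in camera was then 0.0726 for interferons, 0.0886 for interferon-stimulated genes, 0.0977 for maturation, 0.542 for immediate-early genes and 0.0705 for apoptosis. Fry passed for all of these lists but the immediate-early list (adjusted p = 0.123).

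SCAMP5, lower with ODN2216 alone, was higher with the inhibitor than without (1.65 ± 0.22, adjusted p = 0.0074). PI4KB (1.67), C2orf68 (1.47), FLJ42627 (1.29) and ATG2B (1.12) were the other higher genes, and further probe sets of PI4KB, FLJ42627 and ATG2B moved in the opposite direction. Another probe set of SCAMP5 gave 0.23 here and -0.29 with ODN2216 alone. BTK (0.36, adjusted p = 0.717), TLR7 (-0.88, adjusted p = 0.197) and IRF7 (-0.46, adjusted p = 0.41) did not pass. Neither pDC identity nor BTK and ITAM signalling passed camera (adjusted p = 0.443 and 0.459). In all, 43 genes were lower and 5 higher (limma), and 34 of the 43 were among the 223 genes higher with ODN2216, a set called with the same ODN2216 arrays. The number of lower genes was 0 without replicate 1, 74 without replicate 2, 1 without replicate 3 and 24 without replicate 4. It was 12 without the donor block and 0 when only the compared groups were fitted. The number of higher genes was 0 without replicate 1, 5 without replicate 2, 0 without replicate 3 and 3 without replicate 4. It was 3 without the donor block and 0 with only the compared groups, and each of the 5 higher calls was lost in at least 3 settings. Of the 74 lower and 5 higher genes without replicate 2, only 32 and 2 were among those called with all donors.

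The comparison of gardiquimod with and without the inhibitor asks the same of the TLR7 ligand. No gene passed the threshold in limma, in either direction, and 612 of 9570 had an unadjusted p under 0.05. IFNB1 changed by -0.09 ± 0.53 (95% interval -1.21 to 1.03), BTK by -0.11 ± 0.27 (-0.69 to 0.47), TLR7 by 0.27 ± 0.26 (-0.29 to 0.83) and IRF7 by -0.09 ± 0.19 (-0.50 to 0.32). For IFNB1, whose signal with gardiquimod was near the highest value measured, signal saturation stays open. The median change was -0.11 over interferons, 0.03 over interferon-stimulated genes, -0.05 over cytokines, 0.04 over chemokines, 0.02 over maturation, -0.03 over NF-kB and 0.01 over apoptosis genes, and camera passed for none of these lists. It passed for the immediate-early list with a median of -0.26 (adjusted p = 0.0293, 0.663 with an estimated correlation, and 0.394 in fry). DUSP4 was at -1.56 (adjusted p = 0.722) and MYC at -0.91 (adjusted p = 0.774) in that list. The genes with the smallest p, none past the threshold, were MED17 (1.15, adjusted p = 0.439), KRABD4 (1.27), WIPF2 (-1.01), PI4KA (-0.91) and FAM8A1 (higher).

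**Figure D2:**
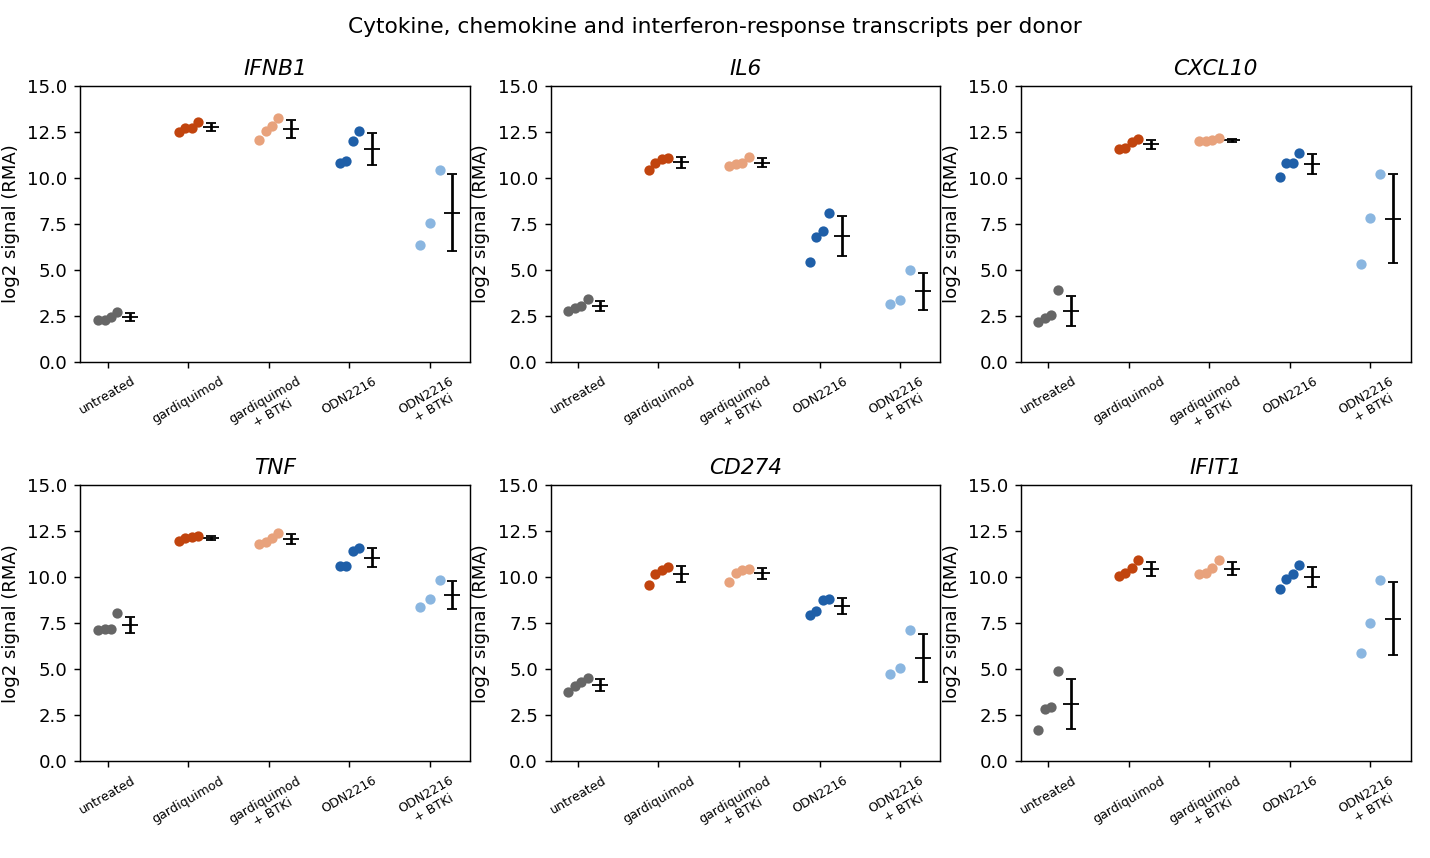
Log2 signal of the plotted cytokine, chemokine and interferon-response transcripts per donor (points) with group means and SD for the 5 treatments. The mean for IL6 is 3.04 in untreated cells, 6.85 with ODN2216 and 3.84 with ODN2216 and inhibitor, and 10.84 with gardiquimod and 10.83 with gardiquimod and inhibitor.

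The difference between the inhibitor effects under the ligands was tested directly. No single gene passed in limma (smallest adjusted p = 0.145, 769 of 9570 with an unadjusted p under 0.05). Without replicate 2, 1 gene was higher and 10 were lower, and with each array as a sample 1 and 18. The estimates were -3.33 for IFNB1 (95% interval -5.00 to -1.66, adjusted p = 0.264), -4.70 for IFNA1 (-7.04 to -2.37), -3.08 for IL6 (-4.29 to -1.88, adjusted p = 0.205), -3.26 for CXCL10 (-4.94 to -1.57) and -2.79 for CD274 (-4.07 to -1.51), each lower under ODN2216 in 3 of 3 donors. CXCL9 (-3.20), RGS1 (-2.22), SCAMP5 (1.77) and GATAD1 (1.79) were, with IL6, the genes with the smallest p, and other probe sets of SCAMP5 and GATAD1 gave 0.58 and 0.0498. Adjusted over the list alone, 10 of 11 interferon genes, 27 of 39 interferon-stimulated genes, 8 of 14 cytokines, 7 of 14 chemokines, 6 of 16 maturation genes, 2 of 17 NF-kB genes and 4 of 14 apoptosis genes were lowered more under ODN2216. Camera passed for each of these 7 lists. With an estimated correlation it held for cytokines (adjusted p = 0.0197), chemokines (adjusted p = 0.0432) and NF-kB (adjusted p = 0.0432). The adjusted p was then 0.103 for interferons, 0.109 for interferon-stimulated genes, 0.108 for maturation and 0.077 for apoptosis. A comparison of the inhibitor effects per donor with no other group, chosen after seeing the data, gave 56 lower and 4 higher genes. It ignores that 3 donors are in both sets of effects, and the fit with a donor block to only the compared groups gave 0 and 0.

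With the inhibitor, the part of the ODN2216 response kept was 31.5% ± 15.8 (SD, n = 3 donors) for cytokines, 34.6% ± 12.6 for chemokines, 32.0% ± 6.5 for NF-kB and 28.9% ± 49.2 for interferon-stimulated genes. The last ran from -23.7% to 73.9% between donors, and the mean ran from 6.4% to 55.2% with a donor left out. Under gardiquimod the parts kept were 98.9% ± 7.9 (SD, n = 4 donors), 101% ± 6.3, 103% ± 11.02 and 101% ± 3.3 in the same order. The 43 genes lowered under ODN2216 had a median inhibitor effect of -2.08 there and of -0.06 under gardiquimod. They were chosen for their fall under ODN2216, which by itself enlarges the first value and not the second. Of the 223 genes higher with ODN2216, 222 were lower with the inhibitor, by any amount (median -1.21). The ODN2216 arrays that defined these genes are also those the inhibitor was compared with, which by itself favours a fall. Of the 1496 genes higher with gardiquimod, chosen in the same way, 985 were lower with the inhibitor (median -0.10). Across genes, the inhibitor effect under ODN2216 correlated with the ODN2216 response (r = -0.72, covariance -0.20), and with r = -0.51 (covariance -0.16) when different ODN2216 arrays were used for each. Simulated unchanged groups that shared arrays gave r = -0.50 with a covariance of -0.05. For gardiquimod r was -0.13 (covariance -0.05), and -0.0379 (covariance -0.02) with the arrays divided, and simulated unchanged groups that shared arrays gave r = -0.50 with a covariance of -0.05. The divided arrays came from the same donors, so a deviation of a donor under a ligand stays in both sides. No simulation was run for divided arrays, so their r values have no simulated value beside them.

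**Figure D3:**
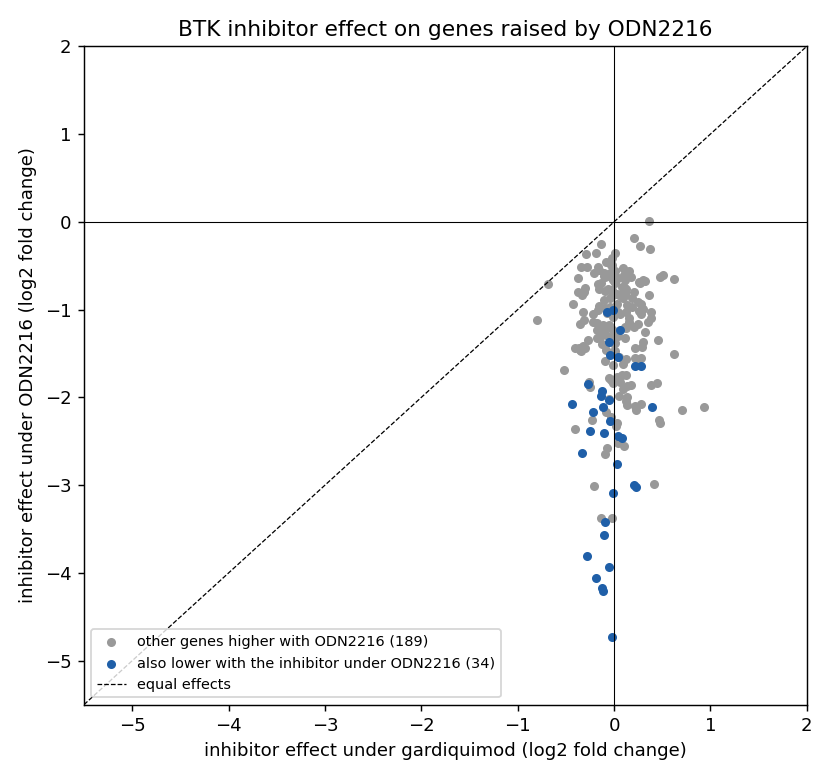
Inhibitor effect (log2 fold change) under gardiquimod (x axis) and under ODN2216 (y axis) for the 223 genes higher with ODN2216, with the 34 that also passed the threshold for the inhibitor in blue and a dashed line of equal effects. Effects reach -4.73 under ODN2216 and -0.80 under gardiquimod.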

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

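The counts of other splits were planned, but the comparison of inhibitor effects per donor that the last of them rests on, and the tests of technical explanations, were chosen after the results were seen.

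As lists, cytokines, chemokines and NF-kB genes were lowered more by the inhibitor under ODN2216 than under gardiquimod, by medians of -1.20, -1.56 and -0.71 (adjusted p = 0.0197, 0.0432 and 0.0432 with an estimated correlation in camera). No single gene passed over all genes in the limma fit with all donors. Adjusted over the list alone, 8 of 14, 7 of 14 and 2 of 17 genes passed in the same order. Signal saturation with gardiquimod was examined in the 7 of 43 inhibited genes that were no brighter with gardiquimod than with ODN2216. Their median inhibitor effect under gardiquimod was -0.046 (SD between donors 0.18) against -1.19 under ODN2216. At least -0.60 was required, or -1.04 on the median of all 43. This cannot decide the question, since 38 of the 43 were higher with gardiquimod and some of the 7 may have had no rise to lower. Of the 43, 16 had a gardiquimod mean above the 99th percentile of all values (10.77), where saturation stays open. All 43 were chosen for their fall under ODN2216, which by itself enlarges their ODN2216 medians. Different donors under the ligands are argued against by the 3 donors with both, in which the 43 genes had a median effect of -0.11 (SD 0.12) under gardiquimod. Stronger stimulation by gardiquimod, with a response 1.16 higher over the 43 genes, cannot be told apart from a difference between the receptors, because each ligand was used at 1 dose and only 5 genes had responses within 0.5 of each other (medians -1.59 under ODN2216 and -0.15 under gardiquimod).

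More genes were lower with gardiquimod (2585) than with ODN2216 (24). After centring each array on its median, 2009 genes were lower with gardiquimod and 22 with ODN2216, which argues against differences between array medians as the cause. A change of all transcripts that RMA had removed could not be seen in this way. As a mark of a lower share of pDCs, a rise by 1.12, the median fall of the pDC list, was required of the markers of 8 other cell types. The median over 39 such markers was 0.14 (SD between donors 0.23), with 5 past the threshold upwards and 3 downwards. This cannot exclude a lower share of pDCs, because the size of such a rise depends on which other cells were present, which is not known. RNA degradation was examined through the 5 prime relative to the middle signal of the actin control probe sets. A fall by 1.13, the median fall of the lower genes, was set as its mark. The actin signal changed by 0.0821 (SD 0.0908, higher in 4 of 4 donors), so it showed no fall. How large a fall degradation would give, and how it would act on other transcripts, was not measured. A difference between the ligand responses, at doses the labels do not give, may account for it and stays a hypothesis.

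Platelet markers varied between arrays of the same treatment, by 4.11 in untreated cells, 3.61 with gardiquimod and 3.78 with ODN2216 in the mean of 9 markers, while arrays of the same donor and treatment differed by at most 0.40. Within treatments, 28 other platelet transcripts outside all gene lists, chosen after the pattern was seen, had a median correlation of 0.90 with that mean (26 of 28 positive). This was above all of 1000 random lists matched on signal (percentile 100, median -0.05, highest 0.18), as platelets among the cells of some donors could give. The arrays came from 4 donors and are not independent, so the correlation rests on few donors. Random lists hold unrelated genes, so any genes that vary together with the markers could reach this percentile. The mean level in untreated cells was 6.27 for PPBP and 5.36 for PF4, no gene of the platelet list is in another list, and the labels name no sort or gate. How far pDCs express these genes was not tested, nor was a biological explanation.

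Of 35 splits of the samples, or of the donors' inhibitor effects for the last count, only the real one (1 of 35) gave as many genes for 5 counts. The real count and the highest of the other splits were 4081 and 0 for gardiquimod, 247 and 2 for ODN2216, 2819 and 1 for ODN2216 against gardiquimod, 48 and 6 for the inhibitor under ODN2216, and 60 and 0 for the inhibitor effects per donor. Every other split mixed the compared groups, so a real difference between them adds to the spread and lowers the count. The other splits thus do not show how many genes unchanged samples would give. The 35 splits also ignore that the donors pair the samples, and the 8 splits that part every pair are too few for a share under 0.05. Among those 8 the highest other was 0, 0, 0, 6 and 0 in the same order. For the inhibitor under gardiquimod the real count was 0, so all 35 splits gave as many, and the highest other gave 2.

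In 15 of 248 groups of 4 donors, 1 donor lay far from the others, where chance gives about 12.4. With gardiquimod against untreated these were 8.85 for IFNA8 (others 9.35 to 9.41), -2.72 for SLC2A1 (-4.25 to -4.18), 2.85 for CMPK2 (6.99 to 7.75), 7.02 for IL12B (6.20 to 6.33), 2.77 for CD80 (5.40 to 5.58) and 1.31 for PRF1 (2.06 to 2.19). With ODN2216 against untreated they were -0.71 for BTK (-0.44 to -0.40), 2.35 for CMPK2 (6.52 to 7.38), 5.25 for IL1B (3.20 to 3.44) and 6.96 for CD69 (4.91 to 5.18). With ODN2216 against gardiquimod they were 2.25 for ATOSA (3.61 to 3.84), -1.74 for HERC6 (-4.05 to -3.66), -2.35 for TNIP3 (-4.18 to -3.87), 0.12 for the BTK and ITAM signalling median (others 0.28) and 0.43 for the unfolded protein response median (0.14 to 0.16).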

How the results depend on the processing

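The platelet covariate and the comparison of inhibitor effects per donor were chosen after seeing the data. The cause of each shift was not tested, except that the setting with all probe sets tests more features and a fold threshold can only lower a count. Calls of named genes were lost in 60 cases and gained in 30 under other settings, and lost in 87 and gained in 10 with a donor left out. Camera calls were lost in 23 cases with an estimated correlation. Without a donor a group kept at least 2 donors, and the spread was pooled over all groups. The counts for the inhibitor under gardiquimod stayed at 0 in every setting run. No detection calls were used, so how signal over background limits dim genes was not measured.

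Counts are given as higher and lower, and settings that moved them less are not listed. For gardiquimod against untreated (1496 and 2585) all probe sets gave 2760 and 4791, and a log2 change of at least 1 gave 886 and 1594. Leaving out each donor gave 1006 to 1526 and 1815 to 2525. For ODN2216 against untreated (223 and 24) all probe sets gave 406 and 93 and each array as a sample 344 and 86. The lower count was 9 with no replicate block, 51 with the mean over probe sets and 48 with only the compared groups. Leaving out each donor gave 128 to 179 and 6 to 29. For the inhibitor under ODN2216 (5 and 43) no replicate block gave 3 and 12, the 30% dimmest left out 8 and 72, each array as a sample 14 and 184, trended and robust moderation 8 and 78, and only the compared groups 0 and 0. All probe sets gave 22 higher, another quantile normalization 12 higher and the mean over probe sets 73 lower. Leaving out each donor gave 0 to 5 and 0 to 74. For the difference between inhibitor effects (0 and 0) each array as a sample gave 1 and 18, inhibitor effects per donor (donors not paired) 4 and 56, and leaving out each donor 0 to 1 and 0 to 10. For ODN2216 against gardiquimod (1811 and 1008) all probe sets gave 3170 and 1866, the platelet covariate 1112 and 561, and a log2 change of at least 1 gave 1052 and 633. Leaving out each donor gave 894 to 1658 and 583 to 844. The correlation of the inhibitor effect with the gardiquimod response went from -0.13 to -0.0379 with the ligand arrays divided. The share of the ODN2216 response of interferon-stimulated genes kept with the inhibitor (28.9%) ran from 6.4% to 55.2% with a donor left out, within its SD of 49.2 between donors.

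Reversed values were all of changes that had not passed. TLR7 with gardiquimod (-0.27) was 0.10 with the mean over probe sets and -0.50 to 0.0857 without a donor, and IRF7 (0.18) was -0.20 after another quantile normalization. With the inhibitor under gardiquimod, BTK (-0.11) was -0.53 to 0.16 without a donor, and IFNB1 (-0.09) was -0.18 to 0.0295 without a donor and 0.13 with the platelet covariate.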

Other observations

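Other gene lists moved in part. Over all genes tested, 42.6% passed the threshold with gardiquimod, 2.6% with ODN2216 and 29.5% between the ligands, so a few calls in a list do not set it apart. Of 17 genes of the unfolded protein and integrated stress response, 2 rose and 2 fell with gardiquimod, with PPP1R15A, which encodes a phosphatase subunit that ends the integrated stress response, at 3.34 ± 0.36 and HERPUD1, an endoplasmic reticulum stress gene, at -2.61 ± 0.22. With ODN2216 PPP1R15A was the 1 gene that rose (2.69 ± 0.36). Of 13 cholesterol synthesis genes 2 rose and 2 fell with gardiquimod, and INSIG1, which encodes a brake on sterol synthesis, rose by 3.18 ± 0.19 in 4 of 4 donors. None passed with ODN2216. Of 9 glycolysis genes 2 rose and 1 fell with gardiquimod, with PKM at 1.37 and SLC2A1 at -3.85, and none passed with ODN2216. Of 15 genes of endosomal Toll-like receptor signalling 1 rose and 3 fell with gardiquimod, including MYD88 (1.51), TIRAP (-2.51) and TRAF3 (-1.25). With ODN2216, 3 of these rose: TASL (1.22), MYD88 (0.98) and IRF7 (0.78), of which MYD88 was lost without replicate 1, 3 or 4 and IRF7 without any 1 donor. TIRAP (1.62) and TRAF3 (1.31) were among 7 of 15 that were higher with ODN2216 than with gardiquimod, and the call of TRAF3 was lost with the platelet covariate, chosen after seeing the data. None of these 4 lists passed camera in either ligand comparison with untreated cells or between the ligands. Fry passed with gardiquimod for Toll-like receptor signalling (adjusted p = 0.0351, downwards) and cholesterol synthesis (adjusted p = 0.0102, upwards), and with ODN2216 for Toll-like receptor signalling (adjusted p = 0.0296, upwards). Between the ligands it passed for Toll-like receptor signalling (adjusted p = 0.000319), the unfolded protein response (adjusted p = 0.0038), both higher with ODN2216, and cholesterol synthesis (adjusted p = 0.0175, lower). The cholesterol synthesis median was only -0.05 there, and positive in 2 of 4 donors. For the inhibitor under ODN2216 the unfolded protein response passed fry (adjusted p = 0.0071, downwards) and not camera (adjusted p = 0.0682). Its median there was -0.08, and positive in 1 of 3 donors.

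The next tests were chosen after the result was seen. ODN2216 reached a median of 66.7% of the gardiquimod response (log2 scale) over 38 interferon-stimulated genes at least 2-fold higher with gardiquimod, against 29.6% over all 886 such genes. A response that ODN2216 scales down alike for all genes is argued against by random gene lists matched on the gardiquimod response, with a median of 35.7% (the list's percentile 100). A signal ceiling is argued against by lists matched on signal with gardiquimod, with a median of 37.9% (percentile 100). Interferon-stimulated genes may thus respond to ODN2216 more fully than other genes that gardiquimod raises, which stays a hypothesis, since genes of a list are not independent. The random lists were matched on response or on signal with gardiquimod alone, and not on the untreated level. No detection calls were used, so an untreated level near the lowest values can affect a share. The median was 74.0% for interferons (percentile 97.8 among lists matched on response and 93.5 among lists matched on signal), 52.4% for cytokines (69.9 and 88.2), 36.2% for chemokines (10.1 and 16.3), 47.8% for NF-kB (85.3 and 38.7), 54.1% for maturation (82.1 and 98.3), 43.8% for apoptosis (91.8 and 40.6) and 29.1% for immediate-early genes (30.1 and 32.9).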
